A study of Mus musculus with 29 samples.

How the data were processed

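Total RNA of the mouse prefrontal cortex and caudate-putamen was measured on 29 Affymetrix expression arrays, 18 of the prefrontal cortex and 11 of the caudate-putamen. The animals were FVB/N mice, the parent strain, and 2 lines on the same background that carry human acetylcholinesterase: TgS mice express the AChE-S variant and TgR mice the AChE-R variant. Per the labels, MPTP, whose metabolite is toxic to dopamine neurons, was given in 4 injections of 20 mg/kg spaced 2 h apart (80 mg/kg in all). In each strain 6 mice received MPTP and 6 received saline (36 mice), and tissue was collected 4 days later. The arrays of the unexposed arm carry the word naive. Whether these are the saline-injected mice, how many mice went into an array, the sex of the mice and the hybridisation dates are not given in the sources used here.

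Region, strain and treatment make 12 groups. The naive prefrontal cortex has 4 arrays per strain, MPTP-exposed TgR caudate-putamen has 1 array, and every other group has 2. The deposited values are log2 signals of probe sets, which the authors made with Affymetrix Power Tools, Affymetrix Expression Console and RMA. Versions and settings, and whether all arrays were summarised in 1 run, are not given in the sources used here. The values were used as deposited, on the log2 scale, with no filter on low signal. No detection calls or raw scans came with the table, so the number of arrays is what limits the precision, and the background signal is unknown.

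The table holds 22690 probe sets. The 64 Affymetrix control probe sets were left out, which leaves 22626 tested, called transcripts here. Of these, 20380 carry a single gene symbol, 691 carry several and 1555 carry none. A gene with several probe sets (12393 genes in all) is represented by the one with the highest mean over all arrays. The mouse Ache probe set reports the mouse gene and was not used to judge the human transgenes. No probe set with a single symbol was found for Chat, the acetylcholine-synthesising enzyme.

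All comparisons came from a single linear model in limma 3.58.1 (R 4.3.3) with a mean for each of the 12 groups and a term for a set of arrays, leaving 16 residual degrees of freedom. The set term exists because the source labels spell the prefrontal region in 2 ways, which parts naive prefrontal replicates 3 and 4 of all 3 strains from the other 23 arrays. Averaged over strains, this term makes the prefrontal MPTP and the regional comparisons rest on naive replicates 1 and 2. Moderated tests were two-sided with default empirical Bayes settings, and p was adjusted by Benjamini-Hochberg over the 22626 transcripts within each of 20 comparisons. An adjusted p under 0.05 is called here. Errors given with ± are standard errors of the log2 difference from this model. Groups with 2 arrays, and the 1 with a single array, are assumed to vary like the rest.

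A collection of 31 gene lists (cell type markers, pathways and complexes) was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within each comparison. Each list count is given over all transcripts and adjusted over the list alone. The test was repeated with a correlation estimated from the data. Of 186 calls, 23 held, and most of these are identified where a list is described. The rule for named genes took Ache, Bche and Chat, the 8 largest called rises and the 8 largest called falls whose arrays did not overlap within at least 1 strain (the 5 smallest p where fewer than 5 transcripts were called), and up to 4 members of each list by smallest p. The genes printed are part of that selection and were picked from it after their values were seen; Th lies outside it. The groups, comparisons, tests for differences, gene lists, naming rule and all alternatives but 1 were chosen before the data were examined. The tests of sex, array batch, normalization, dissection margins, the explanations for Lcn2 and the strain markers were chosen afterwards.

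The alternatives were a fit with no set term, the replicate number as a block, each region fitted alone, replicates 1 and 2 alone, quantile normalization, the 0.25 of transcripts with the lowest mean left out, a trended and robust variance, the estimated correlation, the mean of all probe sets of a gene, and leaving out each array in turn. Added after the values were seen was a fit with 6 naive prefrontal arrays (replicates 1 and 2) left out. Replicate numbers were checked for pairing by correlating the residuals of arrays with the same number across strains. The 12 correlations within the naive prefrontal cortex lay between 0.19 and 0.61, and blocked counts are given for those comparisons. Only arrays with the same number were correlated. A difference shared by replicates 1 and 2 of all strains could also give positive values. These correlations therefore cannot show pairing by number in the naive prefrontal cortex. The other groups have 2 numbers each, and their 7 correlations ran from -0.35 to 0.15. Counts were compared with other splits of the same arrays, up to 100 of them. Single arrays far from their group were sought in the groups of 4 with Dixon's ratio at 0.829.

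The model was tested on simulated data with the design of these arrays and 200 changed genes among 22626. For MPTP in the caudate-putamen it recovered 85.2% of the genes changed 1.5-fold and 97.3% of those changed 2-fold, with 10 false calls among 199. For TgS against FVB/N in the naive prefrontal cortex it recovered 82.4% and 97.3%, with 13 false calls among 197. The shifted list was called in both, beside 2 and 1 lists that had not been shifted. The simulated noise was independent between genes, with a single spread per gene over all arrays. It held no correlated genes and no batch beyond the set term, so these rates do not give the error rates of the real data.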

Results

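Gene expression was profiled in 2 brain regions of FVB/N, TgS and TgR mice, unexposed or 4 days after MPTP. The 29 arrays had median log2 signals between 7.61 and 7.78. Replicates 1 and 2 of the naive prefrontal cortex, 6 arrays over the 3 strains, stood apart from the other 23. In these 6, the Y-linked genes Eif2s3y and Kdm5d read 3.42 to 3.83 and 3.58 to 4.32 on the log2 scale, against 8.41 to 9.20 and 7.20 to 7.76 in the others. Xist, the RNA that silences an X chromosome in female cells, read 8.62 to 10.61 against 6.78 to 7.24. The bioB hybridisation controls of these 6 arrays (7.26 to 7.89) resembled those of the MPTP prefrontal arrays (7.32 to 7.76), while naive prefrontal replicates 3 and 4 (6.48 to 6.97) resembled the caudate-putamen (6.30 to 6.92). The dap poly-A controls read 4.13 to 4.42 in replicates 1 and 2 of FVB/N and TgS, but 7.42 and 7.05 in those of TgR and 7.15 to 7.57 in the MPTP prefrontal arrays. The difference between the 5′ and 3′ actin controls reached -2.30 in these 6 arrays (TgR replicate 2) and at most -1.41 elsewhere. Because of these differences, counts of called transcripts and list members in the prefrontal cortex are given with all 29 arrays and again with the 6 arrays left out, an alternative chosen after the values were seen. For the strain-averaged MPTP and regional comparisons, the set term makes the values from all 29 arrays rest on these 6 naive arrays. Without them the same comparisons rest on naive replicates 3 and 4.

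**Figure D1:**
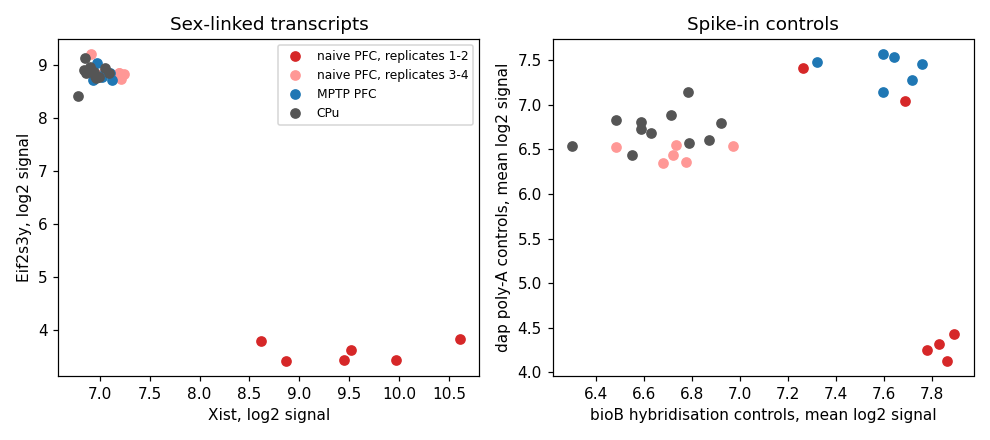
Log2 signals of each array, with Xist against Eif2s3y on the left and the mean bioB hybridisation controls against the mean dap poly-A controls on the right; each point is an array. The 6 naive prefrontal arrays with replicate numbers 1 and 2 have Eif2s3y at 3.42 to 3.83, all other arrays at 8.41 to 9.20.

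The comparison of naive prefrontal cortex with naive caudate-putamen (6 arrays) asks how far the dissected regions differ. All 12 naive prefrontal arrays enter the fit, but the set term makes the differences rest on the 6 that stood apart. Most measured markers of striatal projection neurons and of dopamine signalling were lower in the prefrontal cortex. The dopamine receptor gene Drd2 was 12.7-fold lower (log2 difference -3.67 ± 0.17) and Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, was 6.36-fold lower (-2.67 ± 0.11). Lhx8 and Isl1, transcription factors of striatal and basal forebrain neurons, were 16.4-fold and 14.4-fold lower. Most cortical markers were higher: Neurod6, a transcription factor of cortical pyramidal neurons, 9.79-fold (3.29 ± 0.22), the neuropeptide gene Vip 7.95-fold (2.99 ± 0.12), Cck 6.05-fold and Fezf2, a factor of deep-layer projection neurons, 3.94-fold. Ttr, a product of the choroid plexus, was 37.2-fold lower (-5.22 ± 0.32).

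Of 16 measured striatal projection neuron markers, 13 were lower and 0 higher, also when adjusted over the list alone (camera adjusted p = 4.93e-12; adjusted p = 0.0683 with an estimated correlation). Dopamine receptors and their signalling partners had 8 of 11 lower and 1 higher, with the same counts adjusted over the list alone (camera adjusted p = 5.28e-08; adjusted p = 0.0683 with an estimated correlation). Cortical glutamatergic neuron markers had 17 of 21 higher and 3 lower (4 lower adjusted over the list alone; camera adjusted p = 0.000327; adjusted p = 0.0877 with an estimated correlation). Oligodendrocyte and myelin genes had 15 of 16 lower, again with 15 adjusted over the list alone, among them Mobp (log2 difference -1.93 ± 0.12) (camera adjusted p = 2.67e-12; adjusted p = 0.152 with an estimated correlation). With the 6 arrays left out, 16 striatal markers, 10 of the dopamine receptor list and 16 myelin genes were lower, and 14 cortical markers were higher and 3 lower. Slc18a3, the vesicular acetylcholine transporter, was 3.37-fold lower and mouse Ache 1.52-fold lower (-0.60 ± 0.08) in the prefrontal cortex. Cdhr1 and Tbx21, expressed in olfactory bulb projection neurons, were 9.87-fold and 7.18-fold higher in the prefrontal cortex.

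In all, 13604 transcripts were called in this comparison, 7898 higher and 5706 lower in the prefrontal cortex. Without the set term 4586 were higher and 4487 lower. A fit without the 6 arrays called 12046 and turned the balance, with 5389 higher and 6657 lower; the difference of Drd2 was -4.65 and that of Neurod6 3.69, while meningeal markers went from a median of 0.66 to -0.04 and the immediate early gene Fosb from 1.26 to -0.03.

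The naive strain comparisons ask what the overexpressed acetylcholinesterase variants change without MPTP. In the prefrontal cortex (4 arrays per strain), TgS mice had 4.08-fold less Erdr1 than FVB/N (log2 difference -2.03 ± 0.12), 2.82-fold less Tnnt2, the cardiac troponin T gene (-1.50 ± 0.11), and 2.03-fold less Mocs2, a gene of molybdenum cofactor synthesis (-1.02 ± 0.09). The immunoglobulin heavy chain gene Ighm was 4.21-fold higher (2.07 ± 0.21) and Smarcc1, a subunit of the SWI/SNF chromatin remodelling complex, 5.20-fold higher (2.38 ± 0.33). The chemokine gene Cxcl12 was 2.13-fold lower (-1.09 ± 0.19), the drug efflux pump gene Abcb1a 1.57-fold and the lipid transfer protein gene Pltp 1.60-fold. Gfap, the astrocyte filament gene, was 1.69-fold lower (-0.76 ± 0.16).

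Endothelial and mural cell markers had 9 of 21 members lower in TgS and 10 adjusted over the list alone (camera adjusted p = 0.000116; adjusted p = 0.839 with an estimated correlation). Interferon response genes had 10 of 22 lower, 12 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000116; adjusted p = 0.116 with an estimated correlation), with Ifitm3 1.64-fold lower and the class I histocompatibility gene H2-K1 1.34-fold lower. Meningeal and fibroblast markers had 4 of 15 lower, 8 adjusted over the list alone (camera adjusted p = 0.000116; adjusted p = 0.656 with an estimated correlation). With the 6 arrays left out, 14 endothelial and mural, 6 interferon and 7 meningeal genes were lower. Mouse Ache was 1.24-fold lower (-0.31 ± 0.10, adjusted p = 0.0462), a call that ended without the 6 arrays (-0.10, adjusted p = 0.639).

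For TgS against FVB/N in the prefrontal cortex 2471 transcripts were called, 995 higher and 1476 lower. With the replicate number as a block the count was 1617, without the set term 385, without TgS naive replicate 2 it was 794, and without the 6 arrays 843, where Erdr1 (-2.0), Ighm (2.39) and Cxcl12 (-1.65) were called and Pak3, a kinase gene with 2.21 ± 0.54 over all arrays, was not (0.16, adjusted p = 0.429). Gdpd3, a lysophospholipase D gene, read 9.76 to 10.37 in the other FVB/N arrays, but 5.70 and 5.63 in naive prefrontal replicates 1 and 2 of FVB/N. Of 10 strain markers described under other observations, 6 lay on the TgS side in each of these FVB/N arrays. Their strain identity stays open, which limits the strain comparisons that use them.

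In the naive prefrontal cortex of TgR against FVB/N (4 arrays each), Gpr137b, which encodes a lysosomal membrane protein, was 1.97-fold higher (log2 difference 0.98 ± 0.09, adjusted p = 2.47e-05) and its pseudogene Gpr137b-ps 1.54-fold higher (0.62 ± 0.07). The metallothionein genes Mt2 and Mt1 were 1.44-fold and 1.29-fold higher, and the water channel gene Aqp4 1.33-fold higher. Among genes induced by neuronal activity, Egr1 was 1.66-fold lower (-0.73 ± 0.17) and the phosphatase gene Dusp6 1.52-fold lower (-0.60 ± 0.12). Of 22 immediate early genes 3 were lower, and 8 adjusted over the list alone (camera adjusted p = 4.49e-09; adjusted p = 0.221 with an estimated correlation). Chaperone genes had 0 of 25 called, and 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.68e-06; adjusted p = 0.196 with an estimated correlation). In all 511 transcripts were called, 295 higher and 216 lower. In replicates 1 and 2 the dap controls differed between these strains (7.42 and 7.05 in TgR, 4.13 and 4.24 in FVB/N), as did the 5′ minus 3′ actin controls (-1.30 and -2.30 against -0.95 and -1.04). The count of calls was 10 with the replicate number as a block, 8 without the set term and 11 without the 6 arrays; Gpr137b was called without the 6 arrays (0.69, adjusted p = 0.00399), while Mt2, Egr1 and Dusp6 were not, and 0 immediate early and 0 chaperone genes were. Leaving out 1 array at a time moved the count between 8 (FVB/N naive replicate 1) and 3225 (FVB/N naive replicate 3).

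Between the transgenic lines, TgS prefrontal cortex had less Gfap (2.25-fold, log2 difference -1.17 ± 0.16), less of the glutamate transporter gene Slc1a3 (1.54-fold, -0.63 ± 0.07) and less Vcam1, a cell adhesion gene of vessels and astrocytes (1.62-fold), than TgR. Astrocyte markers had 10 of 18 lower in TgS and 12 adjusted over the list alone (camera adjusted p = 0.000951; adjusted p = 0.443 with an estimated correlation). Immediate early genes had 10 of 22 higher and 1 lower, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.24e-10; adjusted p = 0.24 with an estimated correlation), with Egr1 1.81-fold higher. Erdr1, Tnnt2 and Mocs2 were 2.92-fold, 2.30-fold and 2.25-fold lower in TgS. In replicates 1 and 2 the dap controls read 4.42 and 4.32 in TgS against 7.42 and 7.05 in TgR. In all 4210 transcripts were called, 1580 higher and 2630 lower in TgS, against 3318 with the replicate number as a block, 1704 without the set term, 2086 without TgS naive replicate 2 and 1084 without the 6 arrays, where Gfap (-1.21) and Mocs2 (-1.01) were called and Rbfox1, a splicing factor gene with 2.85 ± 0.61 over all arrays, was not (0.32, adjusted p = 0.531). In that fit 5 astrocyte markers were lower, and 2 immediate early genes were higher and 1 lower.

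In the naive caudate-putamen (2 arrays per strain), TgS differed from FVB/N in several of the transcripts named for the prefrontal cortex and in markers of other brain regions. Erdr1 was 2.97-fold lower (log2 difference -1.57 ± 0.17), Tnnt2 2.70-fold lower and Mocs2 2.51-fold lower, while Ighm was 3.02-fold higher (1.59 ± 0.29) and Glo1, which detoxifies methylglyoxal, 2.90-fold higher (1.53 ± 0.23). Neurod6 was 6.15-fold lower (-2.62 ± 0.39), the cortical transcription factor gene Tbr1 2.77-fold lower and Cck 2.55-fold lower. Slc17a6, the vesicular glutamate transporter of thalamic and other subcortical neurons, was 2.76-fold higher (1.47 ± 0.21), Gbx2, a thalamic transcription factor gene, 1.96-fold higher, and the oxytocin gene Oxt 2.52-fold higher. Mouse Ache was 1.57-fold higher in TgS (0.65 ± 0.14, adjusted p = 0.0145) and Chrnb2, a nicotinic receptor subunit gene, 1.62-fold higher. The difference between the 5′ and 3′ actin controls also went with strain here, at -1.41 and -1.26 in FVB/N, -0.67 and -0.92 in TgS, and -0.87 and -0.99 in TgR.

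Cortical glutamatergic neuron markers had 8 of 21 lower in TgS, and 10 lower and 2 higher adjusted over the list alone (camera adjusted p = 3.09e-06, and 0.0301 with an estimated correlation). Thalamic neuron markers had 4 of 12 higher and 5 adjusted over the list alone (camera adjusted p = 7.52e-10, and 0.0163 with an estimated correlation). Glucocorticoid-responsive genes had 2 of 19 higher and 4 adjusted over the list alone (camera adjusted p = 3.09e-06; adjusted p = 0.361 with an estimated correlation). In all 495 transcripts were called, 298 higher and 197 lower; 2092 were called without the 6 arrays, 1757 with the region fitted alone, 161 without the set term and 69 without FVB/N naive replicate 1 of the caudate-putamen. With the caudate-putamen fitted alone, 0 list calls held with an estimated correlation (smallest adjusted p 0.588).

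Transcripts called in TgS against FVB/N in both regions numbered 47 higher and 65 lower, where independent lists of these sizes would share 13.1 and 12.9. With the 6 prefrontal arrays left out they numbered 105 and 146, against 14.7 and 18.4. They include Ighm, Glo1 and Lsm12, an RNA-binding protein gene, on the higher side and Erdr1, Tnnt2, Mocs2 and Tmem159 on the lower side. In the caudate-putamen Lsm12 was 2.43-fold higher (log2 difference 1.28 ± 0.12).

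**Figure D2:**
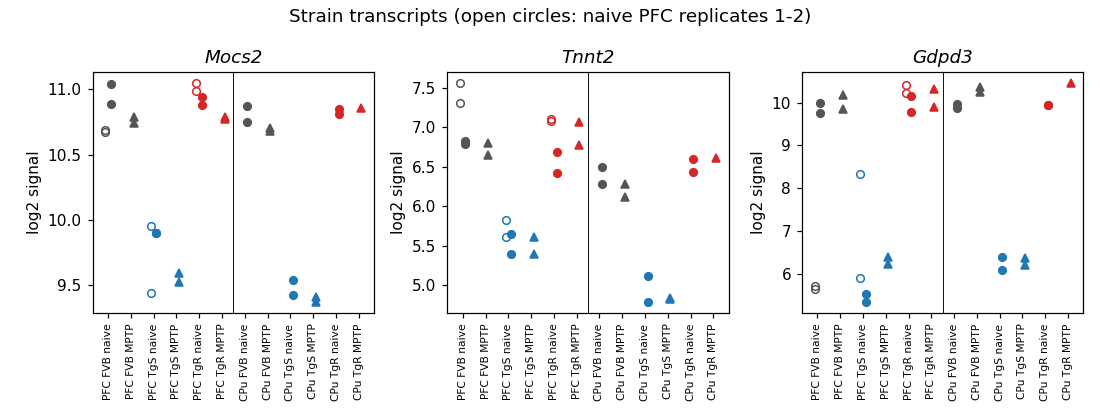
Log2 signals of Mocs2, Tnnt2 and Gdpd3 in each array, by region, strain and treatment; each symbol is an array, circles naive and triangles MPTP, and open circles mark naive prefrontal replicates 1 and 2. Mocs2 and Tnnt2 are lower in every TgS array than in any array of the other strains of that region, while Gdpd3 reads 5.70 and 5.63 in 2 FVB/N arrays.

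In TgR against FVB/N caudate-putamen (2 arrays each) limma called 0 transcripts, with 1066 at an unadjusted p under 0.05. The smallest p values belonged to Gpr137b (log2 difference 0.73 ± 0.13, adjusted p = 0.112), Gpr137b-ps (0.51 ± 0.10, adjusted p = 0.201), Dnajb5, a heat shock protein gene (-0.64 ± 0.13), and Ccn3 (-0.57 ± 0.12), none past the threshold. Choroid plexus and ependymal markers had 0 of 12 called and 8 lower adjusted over the list alone (median -0.91; camera adjusted p = 8.02e-13; adjusted p = 0.0689 with an estimated correlation). Unequal dissection margins could also give lower choroid plexus markers, and were not tested for this comparison. Without the 6 prefrontal arrays, which enter only the estimate of spread here, 92 transcripts were called, among them Gpr137b (adjusted p = 0.000567).

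In the naive caudate-putamen, several choroid plexus genes were higher in TgS than in TgR (2 arrays each). Kl, the klotho gene, was 5.78-fold higher (log2 difference 2.53 ± 0.47), Ecrg4 4.84-fold higher, the folate receptor gene Folr1 2.94-fold higher and Otx2, a transcription factor gene of the choroid plexus, 2.16-fold higher (1.11 ± 0.18). Choroid plexus and ependymal markers had 5 of 12 higher and 10 adjusted over the list alone (camera adjusted p = 1.11e-19, and 0.00981 with an estimated correlation). Thalamic neuron markers had 3 of 12 higher and 6 adjusted over the list alone (camera adjusted p = 9.25e-14, and 0.00391 with an estimated correlation), and chaperone genes 1 of 25 higher and 7 adjusted over the list alone (camera adjusted p = 4.25e-14, and 0.00981 with an estimated correlation). Unequal dissection margins could also give the choroid plexus and thalamic differences, and were not tested for this comparison. Mocs2, Tnnt2 and Erdr1 were 2.55-fold, 2.95-fold and 2.03-fold lower in TgS. In all 175 transcripts were called, 85 higher and 90 lower, against 664 without the 6 arrays, 76 without the set term and 52 without TgR naive replicate 1. With the region fitted alone, 0 list calls held with an estimated correlation.

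The comparison of MPTP with naive arrays asks what the toxin changed 4 days after exposure. In the caudate-putamen, the region that receives the dopamine axons, Lcn2 had the largest rise among the named genes. It encodes lipocalin 2, an iron-siderophore-binding protein of acute inflammation, and rose 11-fold as the mean of the 3 strains (log2 difference 3.46 ± 0.21; 5 MPTP and 6 naive arrays, every MPTP array above every naive one). The calprotectin genes S100a8 and S100a9 rose 3.36-fold and 2.49-fold, Lrg1, an acute-phase glycoprotein gene, 2.17-fold (1.12 ± 0.13) and Osmr, the oncostatin M receptor, 1.81-fold. Microglial genes rose, with the complement genes C1qc at 2.00-fold (1.00 ± 0.13) and C1qa at 1.65-fold and the homeostatic marker Tmem119 at 1.28-fold. Glucocorticoid-induced genes rose as well, among them Sgk1 (1.70-fold, 0.77 ± 0.09), Pdk4, a regulator of glucose oxidation (1.93-fold), and Zbtb16 (1.81-fold).

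Microglia and macrophage markers had 12 of 20 higher and 17 adjusted over the list alone (camera adjusted p = 9.48e-23, and 0.0152 with an estimated correlation). Glucocorticoid-responsive genes, a list that holds Lcn2, had 12 of 19 higher and 16 adjusted over the list alone (camera adjusted p = 4.21e-23, and 0.0137 with an estimated correlation). Meningeal and fibroblast markers had 7 of 15 lower and 10 adjusted over the list alone (camera adjusted p = 1.17e-18, and 0.0137 with an estimated correlation), with the proteoglycan gene Ogn 2.03-fold lower (-1.02 ± 0.16) and Aldh1a2, which makes retinoic acid, 1.71-fold lower. Slc17a6 was 1.95-fold lower (-0.96 ± 0.13) as the mean of the strains. Its response was more negative in TgS than in FVB/N (interaction -2.0), and naive TgS had more of it than naive FVB/N. The mean therefore does not describe each strain. The 15 measured genes of dopamine synthesis, transport and midbrain dopamine neurons had 0 called, over all transcripts and adjusted over the list alone (median -0.015; camera adjusted p = 0.0817). Ddc, which converts L-DOPA to dopamine, differed by -0.22 ± 0.09 (adjusted p = 0.337), and Th, the rate-limiting enzyme of dopamine synthesis, by -0.12 ± 0.38 (adjusted p = 0.953). The midbrain was not sampled, so these values cannot show whether its dopamine neurons were lost or spared. Dopamine receptors and their signalling partners had 0 of 11 called in either way of counting (median 0.028; camera adjusted p = 0.96). Mouse Ache differed by -0.18 ± 0.09 (adjusted p = 0.417). With the caudate-putamen fitted alone, 0 list calls held with an estimated correlation (smallest adjusted p 0.296).

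For MPTP in the caudate-putamen 323 transcripts were called, 200 higher and 123 lower. The count was 1028 without the 6 naive prefrontal arrays (497 higher, 531 lower), 614 with the region fitted alone (293 higher, 321 lower), 205 with the replicate number as a block, 98 without the set term and 155 without TgS MPTP replicate 2.

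**Figure D3:**
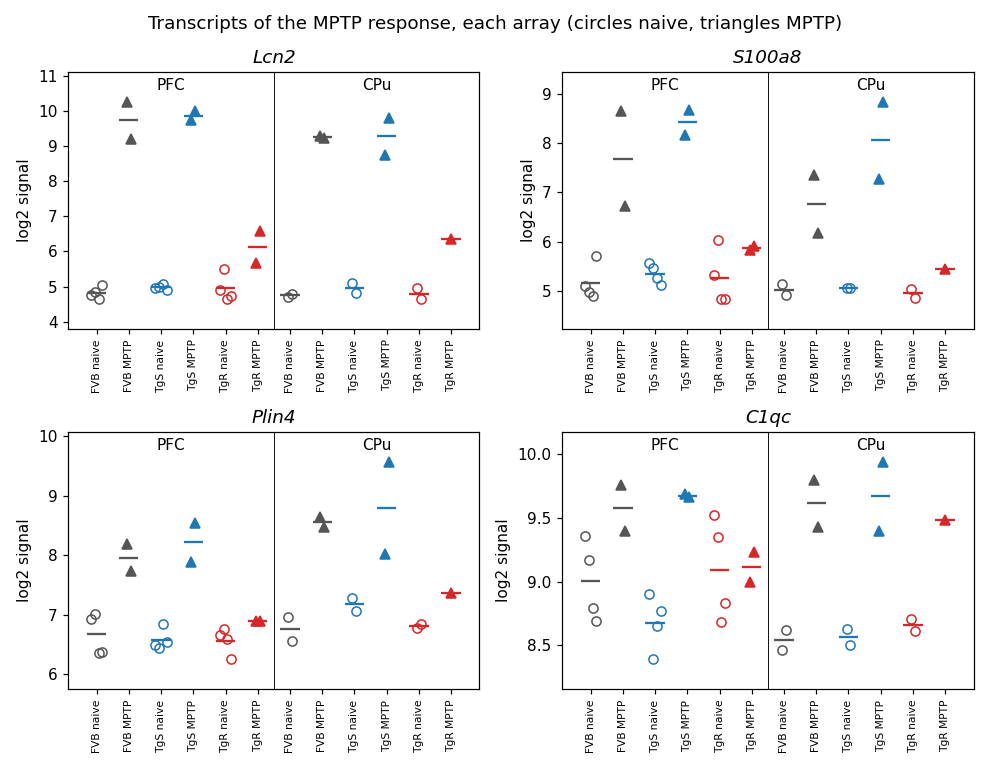
Log2 signals of Lcn2, S100a8, Plin4 and C1qc in each array by region, strain and treatment; circles are naive arrays, triangles MPTP arrays and bars group means. Lcn2 averages 9.26 in FVB/N and 9.28 in TgS caudate-putamen after MPTP and reads 6.35 in the single TgR array.

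Within strains, Lcn2 of the caudate-putamen rose 22.7-fold in FVB/N (log2 difference 4.50 ± 0.34; 2 arrays against 2) and 20.0-fold in TgS (4.32 ± 0.34; 2 against 2). In TgR (1 array against 2) its difference was 1.55 ± 0.41, not called (adjusted p = 0.297). The TgR difference was smaller than that of FVB/N by the interaction test (log2 -2.96 ± 0.53, adjusted p = 0.0188). In FVB/N the chaperone genes Hspa1a and Hspa1b rose 2.94-fold and 1.88-fold (1.55 ± 0.24 and 0.91 ± 0.12), Fkbp5, a glucocorticoid-induced co-chaperone, 1.80-fold, and Mef2c, a neuronal transcription factor gene, fell by 0.49 on the log2 scale (1.40-fold lower). In TgS the cyclooxygenase gene Ptgs2 rose 3.89-fold (1.96 ± 0.21) and Neurod6 4.20-fold, while Calcr, the calcitonin receptor, was 2.56-fold lower, Slc17a6 3.18-fold lower, Oxt 3.23-fold lower and mouse Ache 1.58-fold lower (-0.66 ± 0.14). Neurod6, Slc17a6, Oxt and mouse Ache differed the opposite way between naive TgS and naive FVB/N. Unequal dissection margins between the naive and MPTP arrays therefore stay open for these genes. In TgR the microglial gene Selplg rose 1.45-fold, and Gpx3, an extracellular glutathione peroxidase gene, and Epas1, which encodes HIF-2 alpha, were 2.34-fold and 2.38-fold lower.

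Chaperone genes had 7 of 25 higher in FVB/N and 13 adjusted over the list alone (camera adjusted p = 3e-25, and 0.00167 with an estimated correlation). Glucocorticoid-responsive genes had 9 of 19 higher in FVB/N, 15 adjusted over the list alone (camera adjusted p = 1.78e-30, and 0.00256 with an estimated correlation), and 5 of 19 in TgS, 14 adjusted over the list alone (camera adjusted p = 2.36e-16, and 0.0279 with an estimated correlation). Cortical glutamatergic neuron markers had 3 of 21 lower in FVB/N, 7 adjusted over the list alone (camera adjusted p = 1.52e-10, and 0.00256 with an estimated correlation), but 6 of 21 higher in TgS, 9 adjusted over the list alone (camera adjusted p = 3.97e-07, and 0.0155 with an estimated correlation). Dissection margins stay open for the cortical markers, whose median was lower in naive TgS than in naive FVB/N. Meningeal and fibroblast markers had 9 of 15 lower in TgS, 12 adjusted over the list alone (camera adjusted p = 1.57e-23, and 0.00581 with an estimated correlation). Microglia and macrophage markers had 1 of 20 higher in TgR, Selplg, and 14 adjusted over the list alone (camera adjusted p = 5.14e-21; adjusted p = 0.0596 with an estimated correlation). With the region fitted alone, 0 list calls held with an estimated correlation.

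The calls numbered 60 in FVB/N (45 higher), 318 in TgS (168 higher) and 25 in TgR (6 higher). Without the 6 naive prefrontal arrays they numbered 153, 855 and 112, and without the set term 5, 100 and 1. Without MPTP replicate 2 the FVB/N count was 1 and the TgS count 51.

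**Figure D4:**
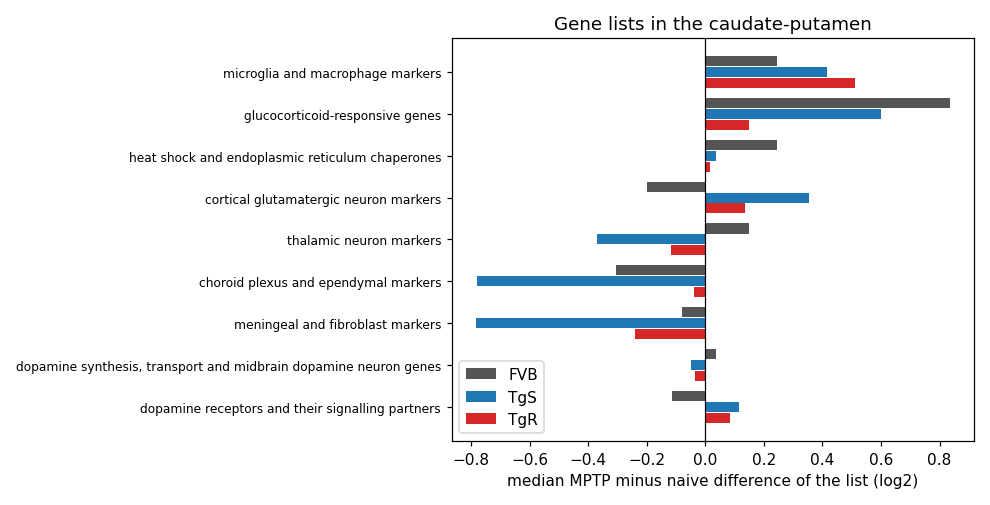
Median MPTP minus naive log2 difference of 9 gene lists in the caudate-putamen, with a bar for each strain; the axis is in log2 units and starts from 0. The microglia list has medians of 0.24 in FVB/N, 0.42 in TgS and 0.51 in TgR, and the glucocorticoid list 0.84, 0.60 and 0.15.

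Tests of the difference between responses in the caudate-putamen called 136 transcripts for TgS against FVB/N and 41 for TgR against FVB/N. The TgR response rests on 1 MPTP array, whose spread is taken from the other groups. For TgS, several cortical markers responded more positively, with Neurod6 at 4.09 ± 0.55, Tbr1 at 2.37 ± 0.31 and Cck at 2.10 ± 0.28 on the log2 scale, while Calcr (-2.06 ± 0.22), Gal, a neuropeptide gene (-1.75 ± 0.20), and mouse Ache (-1.11 ± 0.19) responded more negatively. Neurod6 was lower in naive TgS than in naive FVB/N (-2.62). The medians of TgS minus FVB/N for cortical, thalamic and choroid plexus markers were -0.25, 0.38 and 0.34 in the naive arrays and 0.31, -0.03 and -0.18 in the MPTP arrays. Cortical glutamatergic neuron markers had 7 of 21 higher and 10 adjusted over the list alone (camera adjusted p = 6.99e-16, and 0.000504 with an estimated correlation), and meningeal and fibroblast markers 2 of 15 lower and 8 adjusted over the list alone (camera adjusted p = 1.25e-16, and 0.00963 with an estimated correlation). For TgR, Gpx3 (-1.90 ± 0.21), Sytl4, a vesicle trafficking gene (-1.99 ± 0.30), and Lcn2 responded more negatively and Prss12, the neurotrypsin gene, more positively (1.76 ± 0.29), and cortical glutamatergic neuron markers had 2 of 21 higher and 8 adjusted over the list alone (camera adjusted p = 1.43e-08, and 0.00785 with an estimated correlation). Chaperone genes had 0 of 25 called in both tests and 6 lower adjusted over the list alone in each (camera adjusted p = 1.92e-10 for TgS and 5.54e-17 for TgR, and 0.0265 and 0.00785 with an estimated correlation). Without the 6 arrays the counts were 322 and 133, without the set term 54 and 4, and without FVB/N naive replicate 1 of the caudate-putamen 50 and 13. With the region fitted alone, 0 list calls held with an estimated correlation (smallest adjusted p 0.18).

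In the prefrontal cortex MPTP also raised Lcn2, 12.0-fold as the mean of the 3 strains (log2 difference 3.58 ± 0.19). This estimate sets 6 MPTP arrays against naive replicates 1 and 2 (6 arrays), on which the set term makes it rest. S100a8 rose 3.77-fold (1.92 ± 0.30), Osmr 1.87-fold, the sulfotransferase gene Sult1a1 2.26-fold, Fkbp5 1.42-fold and the clock gene Per3 2.13-fold (1.09 ± 0.07). The respiratory chain genes Ndufb10 and Uqcrh were 1.44-fold and 1.25-fold lower (-0.53 ± 0.04 and -0.32 ± 0.04), the ribosomal protein gene Rpl37 1.53-fold lower and the interferon-induced gene Ifit3 1.48-fold lower. All 10 of these genes kept their direction and were called without the 6 arrays (Lcn2 3.73, Osmr 1.59, Fkbp5 0.87, Per3 0.71, Ndufb10 -0.23), whereas Malat1, a nuclear RNA (2.92 ± 0.14), and Camk2a, a synaptic kinase gene (2.31 ± 0.21), were not (0.08 and 0.21). The 10 were picked after their values were seen, so they do not stand for the other calls. Both fits use the same 6 MPTP arrays, so a batch of these arrays stays possible. Drd2 and Tac1, genes of striatal neurons, were 2.09-fold and 2.33-fold lower in the main fit, against naive replicates 1 and 2. Without the 6 they differed by -0.09 and -0.51 on the log2 scale.

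Complex I subunits had 30 of 33 lower, the same adjusted over the list alone, and 25 lower without the 6 arrays (camera adjusted p = 3.69e-05; adjusted p = 0.865 with an estimated correlation). Ribosomal protein genes had 23 of 24 lower and 1 higher, the same adjusted over the list alone, and 15 lower without the 6 arrays (camera adjusted p = 0.000876; adjusted p = 0.865 with an estimated correlation). Splicing factors had 29 of 48 higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 7.82e-11; adjusted p = 0.142 with an estimated correlation), with Clk1 and Srsf5 2.67-fold and 2.48-fold higher; without the 6 arrays 24 were higher and 11 lower (camera adjusted p = 0.342). Glucocorticoid-responsive genes had 12 of 19 higher, the same adjusted over the list alone, and 17 higher without the 6 arrays (camera adjusted p = 0.000135; adjusted p = 0.865 with an estimated correlation). Mouse Ache differed by -0.10 ± 0.08 (adjusted p = 0.258) in the main fit, which rests on naive replicates 1 and 2. The difference was 0.15 (adjusted p = 0.335) without the set term, which averages all naive arrays, and 0.41 without the 6 (adjusted p = 0.000107).

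For MPTP in the prefrontal cortex 13770 transcripts were called, 5181 higher and 8589 lower, against 8645 without the set term. Without the 6 arrays 11428 were called and the balance turned, with 6454 higher and 4974 lower. Calls of more than 2-fold numbered 840 with all arrays and 77 without the 6, and 21 were in both with the same direction. Of the 840, 483 were called the same way without the 6 at any size and 24 the opposite way. Called in both regions were 72 higher and 74 lower, where independent lists would share 45.8 and 46.7, and 9 and 40 went opposite ways. With the 6 arrays left out 324 higher and 174 lower were shared, against 142 and 117 for independent lists, and 119 and 28 went opposite ways.

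In the prefrontal cortex of each strain, Lcn2 rose 28.6-fold in FVB/N (log2 difference 4.84 ± 0.31; 2 MPTP and 4 naive arrays), 28.1-fold in TgS (4.81 ± 0.31) and 2.14-fold in TgR (1.10 ± 0.31). Lrg1 rose 4.94-fold in FVB/N and 6.22-fold in TgS, and S100a8 5.15-fold and 7.59-fold. Both values of S100a8 exceed its mean over the strains given above, so S100a8 responded less in TgR. In TgR, Hspa1b and Hspe1, both chaperone genes, were 1.55-fold and 1.41-fold lower. The calls numbered 5772 in FVB/N, 9197 in TgS and 9892 in TgR, and 487, 3984 and 2746 without the set term. Without the 6 arrays FVB/N had 4276, TgS 8401 and TgR 5094; without MPTP replicate 1 FVB/N had 2452 and TgR 5137, and without MPTP replicate 2 TgS had 5564.

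The difference between the responses of TgR and FVB/N prefrontal cortex was called for 1 transcript, Lcn2 (2351 transcripts with naive replicates 1 and 2 alone), whose response was 13.4-fold smaller in TgR (log2 -3.74 ± 0.41, adjusted p = 0.000464; -3.47, adjusted p = 0.0164, without the 6 arrays). Chaperone genes had 0 of 25 called and 15 lower adjusted over the list alone (camera adjusted p = 4.22e-16, and 0.0149 with an estimated correlation), and glucocorticoid-responsive genes 1 of 19 lower, Lcn2, and 4 adjusted over the list alone (camera adjusted p = 3.7e-11; adjusted p = 0.136 with an estimated correlation). Without the 6 arrays 16 transcripts were called, with 0 chaperone genes (adjusted p = 0.0819 for the list with an estimated correlation) and 1 glucocorticoid-responsive gene, and without FVB/N MPTP replicate 2 of the prefrontal cortex 11. For TgS against FVB/N limma called 0 transcripts, with 2815 at an unadjusted p under 0.05, and 146 without the 6 arrays and 2457 with naive replicates 1 and 2 alone. The smallest p values included Fmod, a matrix proteoglycan gene (0.88 ± 0.14, adjusted p = 0.0633), and Adgre5, an adhesion receptor gene of leukocytes (0.73 ± 0.13, adjusted p = 0.0707). Meningeal and fibroblast markers had 0 of 15 called and 12 higher adjusted over the list alone (camera adjusted p = 1.17e-09; adjusted p = 0.221 with an estimated correlation), and 5 called higher without the 6 arrays.

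The response of the caudate-putamen, compared with that of the prefrontal cortex over the 3 strains, was more positive for most microglial markers. Laptm5 differed by 0.92 ± 0.10 on the log2 scale, Ly86 by 0.80 ± 0.10 and Selplg by 0.51 ± 0.07, and 16 of 20 microglia and macrophage markers were higher and 1 lower (17 and 1 adjusted over the list alone; camera adjusted p = 0.000292; adjusted p = 0.89 with an estimated correlation). Complex I subunits had 19 of 33 higher and 21 adjusted over the list alone (camera adjusted p = 0.00178; adjusted p = 0.89 with an estimated correlation), with Ndufb10 at 0.52 ± 0.06. Splicing factors had 25 of 48 lower and 2 higher, the same adjusted over the list alone (camera adjusted p = 5.99e-14; adjusted p = 0.0557 with an estimated correlation), with Clk1 at -1.34 ± 0.12; without the 6 arrays Clk1 was at -0.15 and not called. In all 9801 transcripts were called, 5864 higher and 3937 lower, against 2480 without the set term. Without the 6 arrays 7349 were called and the balance turned, with 3161 higher and 4188 lower, and Laptm5 (0.76) and Ly86 (0.52) were called; 15 microglia markers and 11 complex I subunits were higher, and 4 splicing factors higher and 13 lower. Calls of more than 2-fold numbered 899 with all arrays and 59 without the 6.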

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

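The tests of sex, array batch, normalization, dissection margins and the explanations for Lcn2 were chosen only after the results were seen; the search for single arrays apart from their group, the tests of differences between responses and the comparisons with other splits were planned.

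MPTP and naive prefrontal cortex differed in 13770 transcripts (5181 higher, 8589 lower). The sex of 6 naive samples is unlikely to be the whole cause of this count, since 11428 transcripts were called without them (6454 higher, 4974 lower); the scaling between arrays stays open, since quantile normalization, with 13015 calls, moved no count of any comparison by over 1.5 times and so tests little. For the size of changes over 2-fold these 6 samples, by their sex, RNA or batch, are a likely cause, since of 840 such calls 21 were over 2-fold and called the same way without them (77 over 2-fold in all). The direction depended less on them, since 483 of the 840 were called the same way without them at any size and 24 the opposite way. Against the naive replicates 1 and 2 alone 14958 transcripts were called and against replicates 3 and 4 alone 11428, of which 6759 moved the same way in both and 1413 in opposite ways; the same 6 MPTP arrays enter both, so a batch of these arrays could give shared calls too. An array batch and MPTP cannot be told apart for the prefrontal arrays: replicates 1 and 2 share the bioB level of the MPTP arrays but differ from them in sex-linked transcripts and, in FVB/N and TgS, in the dap controls (4.13 to 4.42 against 7.15 to 7.57), replicates 3 and 4 share their sex-linked transcripts but not their bioB level, and no hybridisation dates were given.

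TgS and FVB/N differed in 495 transcripts of the naive caudate-putamen, among them fewer cortical and more thalamic transcripts, which unequal dissection margins could give. In the MPTP arrays of these strains, which are separate dissections, 95.5% (107) of 112 transcripts called the same way in both regions had the same sign, with a median of 0.48 against 0.69 in the naive arrays, which argues against margins for these. Of 383 called in the caudate-putamen and not alike in the prefrontal cortex, 61.6% (236) had the same sign and their median was 0.12 against 0.64, while 63.0% of the transcripts that were not called had the same sign too. For these, margins and strain cannot be told apart with 2 dissections per group. RNA quality stays open as well, since the actin difference of the naive arrays was -1.41 and -1.26 in FVB/N against -0.67 and -0.92 in TgS.

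Lcn2 rose less after MPTP in TgR than in FVB/N, with an interaction of -2.96 in the caudate-putamen. A weaker response of TgR in general stays open: the microglia list rose by a median of 0.51 in the single TgR caudate-putamen array against 0.24 in FVB/N, but the glucocorticoid list rose by 0.15 against 0.84, and the chaperone list, with 0 of 25 members called, responded less in TgR in the caudate-putamen and the prefrontal cortex (adjusted p = 0.00785 and 0.0149 with an estimated correlation, 0.0728 and 0.0819 without the 6 arrays, and 0.392 with the caudate-putamen fitted alone). In the prefrontal cortex S100a8 also responded less in TgR than in FVB/N, though the interaction test there called Lcn2 alone. The single TgR array is unlikely to be the cause, since the Lcn2 interaction in the prefrontal cortex, with 2 TgR arrays after MPTP, was -3.74. The markers used gave little sign of neutrophil RNA in the FVB/N samples. In the caudate-putamen 11 measured markers of a list of 12 changed by a median of 0.08 (highest 0.45, 0 called) where Lcn2 changed by 4.50. In the prefrontal cortex their median was -0.0042, with 1 called. The most abundant of them read 7.37 (Ltf), 7.46 (Csf3r) and 6.91 (Ngp) after MPTP and 7.10, 6.98 and 6.47 in naive caudate-putamen. The background signal is unknown, and S100a8 and S100a9, which neutrophils also express, rose, so these markers cannot exclude neutrophil RNA. That the TgR line induces Lcn2 itself less remains a hypothesis beside a weaker response and neutrophil RNA. Differences in the MPTP dose that reached the brain were not measured.

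The count of calls was compared with other splits of the same arrays. For TgS against FVB/N in the naive prefrontal cortex 1 of 35 splits, the real one with 2471, gave as many. The highest other gave 2105 and parted replicates 1 and 2 from 3 and 4. The real groups hold equal numbers of arrays from both sets. Only 18 splits do so, too few for a share under 0.05, so chance cannot be excluded. The highest other of these 18 gave 729. The splits that part all same-numbered pairs are 8, also too few, and the highest other of them gave 729. The blocked count is 1617. For TgR against FVB/N chance cannot be excluded: 4 of 35 splits gave at least the real 511, the highest 2910. That is several times the real count and points to a structure of the samples; the split of replicates 1 and 2 from 3 and 4 gave 2588, and 2 of the 8 splits that part all pairs gave as many. The blocked count is 10. The dap controls of replicates 1 and 2 read 7.42 and 7.05 in TgR and 4.13 to 4.42 in the other strains, so in these arrays TgR and the sample preparation go together. For TgS against TgR 1 of 35 splits gave 4210, the highest other 2085. The 18 with equal numbers from both sets and the 8 that part all pairs are too few for a share under 0.05. In both, 2085 was the highest other again, and chance cannot be excluded here either. The blocked count is 3318. In 100 splits each, the real split alone gave as many for the regions (13604, highest other 10011) and for MPTP in the prefrontal cortex (13770, highest other 10532). The same held for MPTP in the caudate-putamen (323, highest other 229) and for the difference between the regions' responses (9801, highest other 442). For MPTP in the caudate-putamen chance is unlikely, with the real split the highest of 100. The splits of the others mixed the sets and replicate numbers of the naive prefrontal arrays, so they speak against chance only over splits that ignore both.

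In the 4-array groups, 8 of 263 combinations of a named gene and a group had an array far from the others, where chance gives about 1 in 20. Lhx8 read 5.68 in FVB/N replicate 1 against 4.08 to 4.35 in its group (gap over range 0.831), and Slc18a3 read 6.27 there against 5.62 to 5.64 (0.969). Ppp1r1b read 9.39 in TgR replicate 2 against 9.09 to 9.13 (0.867), and Rpl37 10.46 there against 10.28 to 10.31 (0.833). Mobp read 10.85 in TgR replicate 3 against 11.17 to 11.19 (0.941), Mocs2 9.44 in TgS replicate 1 against 9.90 to 9.95 (0.902), Per2 8.47 in FVB/N replicate 3 against 8.86 to 8.92 (0.867), and Bhlhe40 10.47 in TgR replicate 1 against 10.83 to 10.90 (0.837).

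Responses to MPTP differed between strains or regions by the interaction test. In the prefrontal cortex 1 transcript differed between TgR and FVB/N, Lcn2 (-3.74), and 2351 did with naive replicates 1 and 2 alone. In the caudate-putamen 136 differed between TgS and FVB/N, among them Neurod6 (4.09), Tbr1 (2.37), Cck (2.10), Oxt (-2.39), Calcr (-2.06), Slc17a6 (-2.0), Gal (-1.75), mouse Ache (-1.11), the interferon-induced gene Ifit3 (-0.87) and H2-K1 (-0.65). The naive arms of this test are those with fewer cortical and more thalamic transcripts in TgS, and in the MPTP arrays the medians of TgS minus FVB/N were 0.31 for cortical and -0.03 for thalamic markers against -0.25 and 0.38 in the naive ones. Dissection margins therefore stay open here. Between TgR and FVB/N 41 differed there, with 1 TgR MPTP array whose spread is taken from the other groups, among them Lcn2 (-2.96), Prss12 (1.76), Cck (1.70), Gpx3 (-1.90), Sytl4 (-1.99) and Mef2c (0.75). Between the regions 9801 differed, among them the Y-linked gene Eif2s3y (-5.24), Laptm5 (0.92), Ly86 (0.80), Selplg (0.51), Srsf5 (-1.30), Clk1 (-1.34), Pdk4 (1.15), Ndufb10 (0.52), Rpl37 (0.66), Per3 (-0.88), the GABA-synthesising enzyme gene Gad2 (-1.32) and Rgs16, a regulator of G protein signalling (-0.67). Without the 6 naive prefrontal arrays 7349 differed (3161 higher, 4188 lower), 59 of them over 2-fold against 899 with all arrays, and Eif2s3y (0.05), Clk1 (-0.15) and Pdk4 (0.30) were not called.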

How the results depend on the processing

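Leaving out the 6 naive prefrontal arrays of replicates 1 and 2 was chosen only after the results were seen; the other alternatives were planned. Over 152 counts under settings other than leaving out 1 array, 101 stayed within 1.5 times the reported count and 51 did not. Quantile normalization, leaving out the 0.25 of transcripts with the lowest mean, and the trended and robust variance moved no count of a comparison beyond that factor. The list tests were not run under them. The mean of all probe sets of a gene was run for the list tests alone, and their count stayed within the factor. For named genes and list medians, 11134 of 11724 values kept their direction and their side of the threshold, 557 lost the call, 22 gained it and 11 changed sign. Of the 186 list calls 23 held with an estimated correlation. With the caudate-putamen fitted alone, 0 list calls held with an estimated correlation (smallest adjusted p 0.18). The background signal is unknown, so small differences of dim transcripts cannot be judged by depth.

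Without the 6 arrays, counts fell to 843 for TgS against FVB/N, 11 for TgR against FVB/N and 1084 for TgS against TgR in the naive prefrontal cortex, and to 5094 for MPTP in TgR prefrontal cortex. They rose in the caudate-putamen, to 2092 for TgS against FVB/N, 92 for TgR against FVB/N, 664 for TgS against TgR, and 1028 for the mean MPTP response (153 in FVB/N, 855 in TgS, 112 in TgR). The same fit gave 322 and 133 differing responses of TgS and TgR in the caudate-putamen and 146 and 16 in the prefrontal cortex. These arrays enter the caudate-putamen comparisons through the estimate of spread alone; in the prefrontal cortex fewer arrays are compared as well. Leaving out 1 more array moved these counts further. In the naive prefrontal cortex they were 222 (FVB/N naive replicate 3) to 1561 (FVB/N naive replicate 4), 3 (TgR naive replicate 4) to 11, and 196 (TgR naive replicate 4) to 1295. In the naive caudate-putamen they were 586 (FVB/N naive replicate 1) to 2265, 8 (FVB/N naive replicate 1) to 207 (FVB/N naive replicate 2), and 224 (TgR naive replicate 1) to 683. For MPTP the lowest in the prefrontal cortex were 1601 in FVB/N (MPTP replicate 1), 5494 in TgS (naive replicate 3) and 2492 in TgR (MPTP replicate 1). In the caudate-putamen they were 500 for the mean (TgS MPTP replicate 2), 18 in FVB/N (MPTP replicate 2), 130 in TgS (MPTP replicate 2) and 44 in TgR (naive replicate 2). Differing responses in the prefrontal cortex were 31 (FVB/N naive replicate 3) to 355 (FVB/N naive replicate 4) for TgS and 0 (FVB/N MPTP replicate 1) to 32 (TgS MPTP replicate 1 of the caudate-putamen) for TgR; in the caudate-putamen the lowest were 128 and 45 (FVB/N MPTP replicate 2).

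Without the set term, counts fell in the naive prefrontal cortex to 385 (TgS against FVB/N), 8 (TgR against FVB/N) and 1704 (TgS against TgR), and in the naive caudate-putamen to 161 (TgS against FVB/N) and 76 (TgS against TgR). For MPTP they fell to 8645 in the prefrontal cortex (487 in FVB/N, 3984 in TgS, 2746 in TgR) and 98 in the caudate-putamen (5 in FVB/N, 100 in TgS, 1 in TgR). Differing responses fell to 54 for TgS and 4 for TgR in the caudate-putamen, and to 2480 between the regions. The set term does not enter the caudate-putamen estimates, so the counts there fell through the shared estimate of spread alone. For the comparisons that use the prefrontal cortex the cause was not tested.

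With the replicate number as a block, counts fell to 1617 (TgS against FVB/N) and 10 (TgR against FVB/N) in the naive prefrontal cortex, to 329 for TgS against FVB/N in the caudate-putamen, to 205 for MPTP there (37 in FVB/N, 7 in TgR), and to 20 for the differing response of TgR. The cause was not tested. With each region fitted alone, the caudate-putamen gave 1757 (TgS against FVB/N), 15 (TgR against FVB/N), 341 (TgS against TgR) and 614 (MPTP), and the naive prefrontal cortex 1186, 10 and 2737. Replicates 1 and 2 alone gave 5302, 7234 and 7729 in the naive prefrontal cortex and 2457 and 2351 differing responses of TgS and TgR there. For the caudate-putamen fitted alone only the estimate of spread changes. For the prefrontal cortex the cause was not tested.

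Values that changed sign without the 6 arrays were Eif2s3y (0.04 between regions, -0.057 for MPTP in the prefrontal cortex, 0.053 for the difference of responses), Fosb (-0.028 between regions), mouse Ache for MPTP in the prefrontal cortex (0.41), the vascular gene Rgs5 for MPTP in TgR prefrontal cortex (0.18, from -0.78), and the medians of the meningeal list between regions (-0.042) and of the striatal list for MPTP in the prefrontal cortex (0.042). For Eif2s3y the cause lies in the 6 arrays, which lack Y-linked signal; for the others the cause was not tested. Mouse Ache was at 0.15 for MPTP in the prefrontal cortex without the set term, and the median of the dopamine synthesis list for MPTP in the caudate-putamen ranged from -0.04 (without TgS naive replicate 2) to 0.0083 (without TgS naive replicate 1 or TgR naive replicate 1 of the caudate-putamen); the cause was not tested.

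Leaving out 1 array at a time, with the array behind the lowest and the highest count, gave for the naive prefrontal cortex 794 (TgS naive replicate 2) to 3147 (TgR naive replicate 2) for TgS against FVB/N, 8 (FVB/N naive replicate 1) to 3225 (FVB/N naive replicate 3) for TgR against FVB/N, and 2086 (TgS naive replicate 2) to 5409 (TgR naive replicate 3) for TgS against TgR. In the naive caudate-putamen it gave 69 (FVB/N naive replicate 1) to 662, 0 to 4 and 52 (TgR naive replicate 1) to 233. For MPTP in the prefrontal cortex it gave 2452 (MPTP replicate 1) to 6229 in FVB/N, 5564 (MPTP replicate 2) to 9634 in TgS and 5137 (MPTP replicate 1) to 10184 in TgR. For MPTP in the caudate-putamen it gave 155 (TgS MPTP replicate 2) to 413 for the mean, 1 (MPTP replicate 2) to 95 in FVB/N, 51 (MPTP replicate 2) to 398 in TgS and 6 (TgR naive replicate 1) to 34 in TgR. Differing responses ranged in the prefrontal cortex over 0 to 5 (TgS) and 1 to 11 (TgR), and in the caudate-putamen over 50 (FVB/N naive replicate 1) to 165 (TgS) and 13 (FVB/N naive replicate 1) to 68 (TgR). Counts between regions, for the mean MPTP response in the prefrontal cortex, for the difference of the regions' responses and for the list tests stayed within 1.5 times. The single TgR MPTP array of the caudate-putamen cannot be left out of the 4 comparisons that need it.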

Other observations

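The check of the strain markers was chosen only after the results were seen; the test of neighbouring genes was written before its result. Some changes after MPTP lay outside the groups described so far. In the caudate-putamen, over the 3 strains (5 MPTP and 6 naive arrays), the transcription factor gene Cebpd rose 2.14-fold (log2 difference 1.09 ± 0.17), Cd14, a co-receptor for bacterial lipopolysaccharide, 1.99-fold, the von Willebrand factor gene Vwf of endothelial cells 1.63-fold, Plin4, which coats lipid droplets, 2.51-fold and the astrocyte glutamate transporter gene Slc1a2 1.32-fold, while Aqp4 was 1.33-fold lower. Reactive astrocyte genes had 3 of 19 higher and 5 adjusted over the list alone (camera adjusted p = 0.000468; adjusted p = 0.227 with an estimated correlation). Choroid plexus and ependymal markers had 0 of 12 called and 8 lower adjusted over the list alone (camera adjusted p = 1.32e-09; adjusted p = 0.1 with an estimated correlation). In TgS caudate-putamen (2 arrays against 2) the clock genes Npas2 and Arntl rose 1.68-fold and 1.51-fold, the synaptic pentraxin gene Nptx1 2.13-fold, and 3 of 12 thalamic neuron markers were lower, 5 adjusted over the list alone (camera adjusted p = 2.14e-08, and 0.0155 with an estimated correlation); 2 of 12 choroid plexus and ependymal markers were lower there, 10 adjusted over the list alone (camera adjusted p = 3.82e-13, and 0.0279 with an estimated correlation). Dissection margins stay open for the thalamic and choroid plexus markers of TgS, whose medians were higher in naive TgS than in naive FVB/N. In TgR caudate-putamen (1 array against 2) the cystatin gene Cst7, a marker of activated microglia, rose 1.48-fold and the retinol-binding protein gene Rbp4 1.66-fold, and Resp18, a neuroendocrine secretory granule gene, was 2.21-fold lower.

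In the prefrontal cortex, over the 3 strains (6 MPTP arrays against naive replicates 1 and 2), the adhesion gene Icam1 rose 1.41-fold (log2 difference 0.50 ± 0.10). The interferon signalling gene Stat2 rose 1.94-fold (0.95 ± 0.09) and the clock gene Arntl 1.46-fold (0.54 ± 0.07). Without the 6 arrays the log2 differences were 1.06 for Icam1, 0.41 for Stat2 and 0.28 for Arntl. Maoa, which degrades monoamines, and Qdpr, which regenerates the cofactor of dopamine synthesis, were 1.17-fold and 1.35-fold lower (-0.22 ± 0.05 and -0.43 ± 0.06; -0.28 for both without the 6 arrays). In TgS prefrontal cortex the complement gene C1qb rose 2.09-fold and Ifit3 was 1.93-fold lower.

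The second FVB/N naive caudate-putamen array carries a description that calls it MPTP-exposed, against its title and treatment label. Its Lcn2 read 4.79, the other naive FVB/N array 4.71, and the MPTP arrays 9.28 and 9.23.

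The 10 transcripts with the largest naive TgS against FVB/N differences, among those called the same way in both regions in the other 23 arrays, were read in naive prefrontal replicates 1 and 2. TgR took no part in their choice. An array was put on the TgS side where it was closer to the TgS mean than to the mean of the other strains. All 10 lay on the TgS side in TgS replicate 1 and 6 of 10 in TgS replicate 2; 6 of 10 lay there in each of the FVB/N arrays, and 0 in each of the TgR arrays. Baiap2l1, a regulator of the actin skeleton, read 8.38 and 8.06 in FVB/N replicates 1 and 2, and 5.71 and 5.87 in FVB/N replicates 3 and 4. Mocs2 read 10.69 or less in the former and 10.89 or more in the latter, against at most 9.95 in TgS. The markers disagree, so the strain identity of FVB/N replicates 1 and 2 and of TgS replicate 2 stays open. Comparisons that use these arrays carry this limit.

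A hypothesis for the transcripts called the same way in TgS and FVB/N in both regions is that they lie near each other on the chromosomes, as carried-over or inserted segments could give. Of their 64 genes, 6 pairs lay within 10 measured genes of each other, among them Eri2 and Tmem159, Ighm and Zfp386, and Mad2l1 and Gng12. Random sets of as many measured genes had a median of 3 such pairs and a 95th percentile of 6, and 1044 of 10000 sets had at least 6 (permutation p = 0.104, one-sided), so the test gave no sign of clustering beyond chance. Single pairs from a shared segment were not tested.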
